A study of Mus musculus with 12 samples.

How the data were processed

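Liver RNA of 12 mice was hybridised to Affymetrix arrays, 3 per group, from 200 ng of RNA with an integrity number above 7, per the labels' protocols. The deposited values were log2 expression levels per probe set made by RMA, per the submitters' processing notes. The software, its version, the array's probe annotation and the genome build are not given in the sources used here. RMA subtracts background, equalises the distribution of all arrays and summarises probes of a probe set on the log2 scale, so a general shift of all genes in a group would be removed and changes of dim probe sets are compressed. Values ran from 1.62 to 13.96. Signal over background was not given, so no detection call was made. Levels close to or under the array medians are not shown to be above background. A log2 change against such a level is a difference of the deposited values, whose true size and rank are uncertain.

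The table holds 41345 probe sets. A platform annotation named exactly 1 gene for 23521 of them and several for 1814, and did not list 16010, which are unnamed here. Gene identifiers of 23328 named probe sets were found in a RefSeq gene table and 193 were not, and 0 symbols had to be updated. A gene was represented by its probe set with the highest mean over all arrays, which left 22180 genes, of which 1082 had more than 1 probe set. Probe sets of Cyp2c29 differed in sign with fasting in Adeno-GFP livers (-0.60 and 0.23), and those of Cyp2c55 (-2.49 and -0.385), Fam107a (1.93 and 0.64) and Col1a2 (-0.55 and -0.03) differed in size. No coordinates are given because the build is not known. Trp53 and Gls2, which had been chosen for the text, have no probe set naming them alone and were not analysed here.

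Groups were taken from the labels. The 12 arrays were fitted together in limma 3.58.1 (R 4.3.3) with a mean per group and moderated with eBayes without trend or robust options, and contrasts were tested for Adeno-Cre against Adeno-GFP in each diet and averaged, for fasted against fed after each injection, and for the interaction. P-values were adjusted by Benjamini and Hochberg over 22180 genes within each contrast, with a threshold of 0.05. Of 33 gene lists, 32 with at least 5 measured members were tested with camera, limma's set test, at a preset correlation of 0.01, and again with a correlation estimated from the residuals of each list; p-values were adjusted over the 32 lists. With the estimated correlation, the pericentral calls of fed mice and of the average over diets held, and the other camera calls did not. The gene lists tested with camera, the comparisons, the rule for naming genes, the thresholds and the alternatives were chosen before the data were examined. The exceptions were fry, another set test of limma, and the test of hepatocyte share with its fits leaving out an array. These exceptions were chosen after the results were seen. Lists cover p53 targets, fasting metabolism, lipid, sterol and bile acid synthesis, stress responses, interferon, the acute phase, cell cycle, clock, hepatocyte zones and the other cell types of liver, and some share genes with others (8 of 16 pericentral genes and 4 of 46 amino acid genes are on another list). The medians, means and tests of lists differed in sign in 27 of 192 cases, 0 of them called.

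Genes were named by a rule: in each comparison up to 8 with the largest rise and 8 with the largest fall among those past the threshold whose groups did not overlap, leaving out predicted genes; up to 4 members with the smallest p of each list called or holding at least 2 members past the threshold; and a fixed set of p53 targets and fasting genes.

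The fit was tested on simulated data with the levels and spread of the real genes, drawn independently for each gene, with 50 genes changed at each of 4 sizes. At changes of 0.5, 1, 2 and 3 it recovered 58%, 96%, 98% and 100% for Adeno-Cre in fasted mice (5.88% of 187 calls were false), 60%, 100%, 100% and 100% in fed mice (3.74% of 187), 56%, 98%, 100% and 100% for fasting after Adeno-GFP (5.85% of 188) and after Adeno-Cre (5.35% of 187), and 12%, 86%, 98% and 100% for the interaction (4.52% of 155). Camera recovered a list shifted by 0.5 (adjusted p = 7.7e-36) and called 1 other list. Real genes of a list move together, with an estimated correlation of 0.644 for endothelial markers. The simulations therefore do not test camera's preset correlation, or the false calls of the fit, on correlated genes. The rates also depend on the 200 genes changed at once, since the adjustment is stricter where fewer genes change.

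The alternatives left out dim probe sets, normalised the arrays again by quantiles, added the replicate number as a block, fitted only the groups compared, used a trended and robust variance prior, averaged the probe sets of a gene, tested all probe sets, and left out each array in turn; for gene lists the prior was trended only, since camera takes no robust one. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures. Bootstrap intervals of list medians used 10000 draws of genes, taken as independent, at 95%. The 20 genes expressed by all leukocytes were listed after the comparisons were seen and before their own values were. Labels give no batch or array date, so none could be tested.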

Results

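Liver RNA of 12 male mice aged 2 months, all carrying floxed alleles of p53 (the Trp53 gene, a transcription factor that restrains cell division and also acts on metabolism), was measured on Affymetrix arrays. Mice received an adenovirus expressing Cre recombinase (Adeno-Cre), which removes the floxed part of the gene in infected cells, or an adenovirus expressing green fluorescent protein (Adeno-GFP). Diet began 3 days later: mice were fasted for 24 h or fed freely. The 4 groups held 3 arrays each, so the number of arrays limits the precision. Array medians lay between 6.26 and 6.33 on the log2 scale, and arrays of a group correlated at 0.991 to 0.994 over all genes. The p-values measure the spread between these arrays. The injections differed in the cargo of the virus as well as in p53, and viral load was not analysed here.

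The first question was whether p53 itself and its known targets were lower after Adeno-Cre. Trp53 was not analysed here, because no probe set of the annotation used names it alone, so the labels could not be checked on the targeted gene. Among 32 measured genes of a list of p53 targets, Ccng1 (cyclin G1; probe set 17261865) averaged 10.55 ± 0.10 (SD, n = 3) in Adeno-Cre fed livers against 11.13 ± 0.09 in Adeno-GFP fed livers, and 10.52 ± 0.11 against 11.02 ± 0.11 in fasted livers. It fell by 0.58 (SE 0.09, limma adjusted p = 0.0135) in fed and by 0.50 (SE 0.09, adjusted p = 0.00986) in fasted mice. Dcxr, which encodes a carbonyl reductase of sugar metabolism, fell by 0.70 (SE 0.08, adjusted p = 0.00592) in fed and by 0.55 (SE 0.08, adjusted p = 0.00352) in fasted mice. Plk2, a kinase, fell by 0.73 in fed mice (adjusted p = 0.0273) and Sesn1, a stress-induced regulator of growth signalling, by 0.37 in fasted mice (adjusted p = 0.0439). Cdkn1a, the inhibitor of cyclin-dependent kinases best known as a p53 target, did not pass: its log2 change was -0.68 (SE 0.33, adjusted p = 0.445) in fed and -0.45 (SE 0.33, adjusted p = 0.536) in fasted mice. Mdm2, which encodes the ubiquitin ligase that degrades p53, had changes of -0.28 (adjusted p = 0.171) and -0.08 (adjusted p = 0.688).

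Of the 32 p53 targets, 3 fell and 0 rose in each diet by limma. Adjusted over the list alone, 7 fell in fed mice, and 9 fell and 1 rose in fasted mice. At an unadjusted p under 0.05, 2742 genes of all kinds passed in fed mice and 3711 in fasted mice. The list median was -0.11 in fed mice (camera adjusted p = 0.000147, and adjusted p = 0.0947 with an estimated correlation). In fasted mice it was -0.15 (camera adjusted p = 0.000748, and adjusted p = 0.242 with an estimated correlation). Without Adeno-GFP fed replicate 1, the members that fell in fed mice numbered 1 and Ccng1 missed the threshold there (adjusted p = 0.0604). Dcxr passed in both diets without each array in turn; Plk2 lost its call without any 1 of the 6 arrays of fed mice, and Sesn1 its call without any 1 of 11 arrays, all but Adeno-Cre fasted replicate 3.

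The second question was what Adeno-Cre changed in fasted livers. Genes of cell division rose together. Shcbp1, a protein of the dividing cell's midbody (probe set 17507288), rose, with deposited log2 levels of 8.88 ± 0.14 (SD, n = 3) after Adeno-Cre and 5.49 ± 0.87 after Adeno-GFP, a difference of 3.39 (SE 0.32, limma adjusted p = 0.00028) whose size is uncertain because the lower level is not shown to be above background. Of 37 measured genes of the cell cycle list, 33 rose and 0 fell, with a median log2 change of 1.48 (camera adjusted p = 2.92e-51, and adjusted p = 0.135 with an estimated correlation). Adjusted over the list alone, 35 rose. Gstm3, a glutathione transferase, was 3.48-fold higher (log2 1.80, SE 0.15, adjusted p = 0.000222).

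In the deposited values, the largest rises after that of Shcbp1 were of Depdc1a (3.02), Ect2 (2.69, a guanine nucleotide exchange factor of cytokinesis), Nuf2 (2.55, a kinetochore protein), Hmmr (2.53), Prc1 (2.43, a midzone microtubule protein), Top2a (2.42, topoisomerase II) and Kif11 (2.38, the mitotic kinesin). Cdk1, the kinase that drives entry into mitosis, rose by 2.26 and the checkpoint kinase gene Bub1 by 2.34. The largest falls were of Ces3b (-1.21, a carboxylesterase), Gadd45g (-1.01), Cxcl13 (-0.88, a B cell chemokine), Retreg1 (-0.77), Wnt3a (-0.75), Lyz2 (-0.71, macrophage lysozyme), Mbl1 (-0.71, a secreted lectin) and Hal (-0.69, histidine ammonia-lyase). For Shcbp1, Depdc1a, Hmmr, Bub1, Cxcl13 and Wnt3a the lower group mean lay under 6.26, the lowest array median, so the sizes and ranks of these changes are uncertain.

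Metabolic lists shifted by less. Of 46 genes of amino acid breakdown, 3 fell and 0 rose (14 fell and 1 rose adjusted over the list alone), with a median of -0.20 (camera adjusted p = 6.96e-09, and adjusted p = 0.342 with an estimated correlation). Those 3 were Hal, Aass (-0.54, the first enzyme of lysine breakdown) and Hpd (-0.39, of tyrosine breakdown). Among 16 pericentral hepatocyte markers, 3 fell and 0 rose (8 fell adjusted over the list alone), with a median of -0.23 (camera adjusted p = 6.4e-05, and adjusted p = 0.135 with an estimated correlation): Gulo (-0.52), Slc1a2 (-0.42, a glutamate transporter) and Rgn (-0.30). Of 19 cholesterol synthesis genes, Hsd17b7 (-0.52) and Msmo1 (-0.53) fell and 0 rose (5 fell adjusted over the list alone; median -0.18, camera adjusted p = 0.00902, and adjusted p = 0.446 with an estimated correlation). Ribosome biogenesis genes had a median of 0.15 (camera adjusted p = 2.68e-06, and adjusted p = 0.235 with an estimated correlation). Of these 31 genes 2 rose, Nop58 (0.49) and Dkc1 (0.40), and 3 rose adjusted over the list alone. Of 38 interferon response genes, Cxcl10 (1.11) and Igtp (0.81) rose and 0 fell (4 rose adjusted over the list alone; median 0.16, camera adjusted p = 9.11e-05, and adjusted p = 0.578 with an estimated correlation). Markers of hepatic stellate cells had a median of -0.24 with 0 of 20 past limma's threshold (5 fell adjusted over the list alone; camera adjusted p = 5.38e-05, and adjusted p = 0.342 with an estimated correlation). Kupffer cell markers had a median of -0.20 (camera adjusted p = 0.0537).

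The gluconeogenesis list gave no call in fasted mice (median -0.15, camera adjusted p = 0.219). Pck1, the rate-limiting enzyme of gluconeogenesis, changed by -0.31 (SE 0.17, adjusted p = 0.38), G6pc by -0.26 (adjusted p = 0.71), Ppargc1a by -0.23 (adjusted p = 0.536), the tyrosine aminotransferase gene Tat by -0.32 (adjusted p = 0.517) and the urea cycle enzyme gene Cps1 by -0.07 (adjusted p = 0.658). Of the 18 genes 1 fell and 0 rose (1 fell adjusted over the list alone): Slc37a4, the glucose-6-phosphate transporter, with a change of -0.445 (adjusted p = 0.0277), named here after its values were seen. The count was 0 without Adeno-Cre fasted replicates 2 or 3 or Adeno-GFP fasted replicates 1 or 2.

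In all, 609 of 22180 genes passed limma's adjusted p of 0.05 in fasted mice, 502 higher and 107 lower, and 142 rose and 3 fell by at least 2-fold. Of the 41 named genes that passed, 21 did so without each array in turn. The count was 355 without Adeno-Cre fasted replicate 2 and 385 without Adeno-GFP fasted replicate 2. Leaving out each array in turn left 30 to 34 cell cycle genes past the threshold. The amino acid members numbered 1 without Adeno-Cre fasted replicate 2 or any of Adeno-GFP fasted replicates 1, 2 and 3 and 5 without Adeno-Cre fasted replicate 1. The pericentral members numbered 0 without Adeno-Cre fasted replicate 1 or Adeno-GFP fasted replicate 1 and 1 without Adeno-Cre fasted replicates 2 or 3 or Adeno-GFP fasted replicate 2. The interferon median was 0.04 without Adeno-GFP fasted replicate 2 and 0.24 without Adeno-GFP fasted replicate 3, and its members numbered 0 without Adeno-Cre fasted replicates 1 or 2 or Adeno-GFP fasted replicate 2, and Cxcl10 also missed the threshold without Adeno-Cre fasted replicate 3. The cholesterol members numbered 4 without Adeno-Cre fasted replicate 3 and 1 without any of the other arrays except Adeno-GFP fasted replicate 3, and the ribosome biogenesis members 1 without Adeno-Cre fasted replicate 2 or Adeno-GFP fasted replicate 3.

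**Figure D1:**
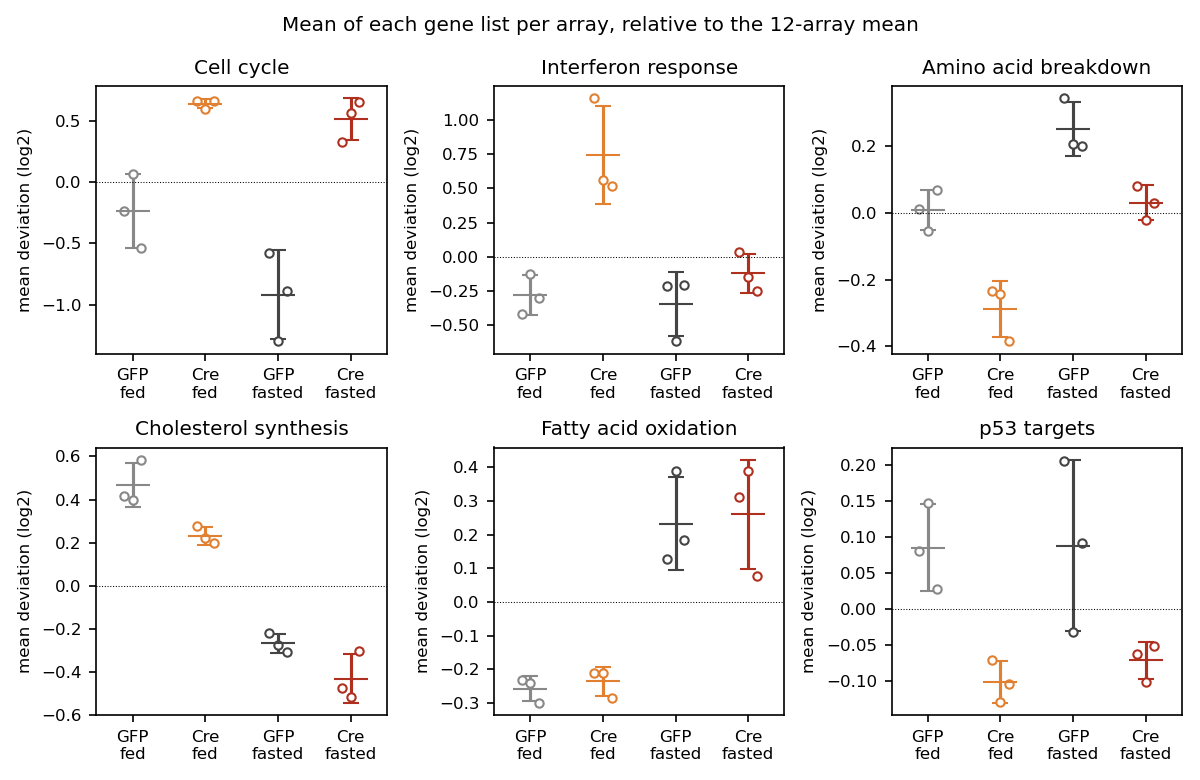
Scores of 6 gene lists on each array, with the 4 groups on the horizontal axis and the mean log2 level of the list's genes, each centred on its mean over the 12 arrays, on the vertical axis. Points are arrays, horizontal lines are group means and bars are the SD (n = 3). The cell cycle score averaged 0.52 in Adeno-Cre fasted livers and -0.92 in Adeno-GFP fasted livers, and the interferon score 0.75 in Adeno-Cre fed livers and -0.28 in Adeno-GFP fed livers.

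The third question was what Adeno-Cre changed in fed livers. Genes induced by interferon rose: of 38 measured, 23 rose and 0 fell, with a median log2 change of 1.07 (camera adjusted p = 2.64e-44, and adjusted p = 0.0947 with an estimated correlation). Gbp10, an interferon-induced GTPase, was 3.46-fold higher (log2 1.79, SE 0.24, limma adjusted p = 0.00706), and Igtp, of the immunity-related GTPases, 2.80-fold higher (log2 1.48, SE 0.17, adjusted p = 0.00537). Ifit1, which binds foreign RNA (probe set 17358832), averaged 10.10 ± 0.76 (SD, n = 3) after Adeno-Cre and 8.10 ± 0.23 after Adeno-GFP. Cell cycle genes rose here too, 15 of 37 with 0 lower (median 1.03, camera adjusted p = 2.5e-30, and adjusted p = 0.0947 with an estimated correlation). Genes of amino acid breakdown fell, 9 of 46 with 0 higher (median -0.28, camera adjusted p = 1.23e-20, and adjusted p = 0.0947 with an estimated correlation). Adjusted over the list alone, 33 interferon genes rose, 28 cell cycle genes rose and 2 fell, and 29 amino acid genes fell.

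The largest rises were of Ifit1 (2.01), Oas1g (1.94), Zbp1 (1.87, a sensor of nucleic acid), Isg15 (1.87, a ubiquitin-like protein), BC023105 (1.86), Gbp10, Shcbp1 (1.79) and Prc1 (1.74). Other interferon genes that rose were Rtp4 (1.41), Irgm2 (1.23) and Irgm1 (1.22), and other division genes Bub1 (1.54), Cdk1 (1.46), Bub1b (1.38) and Aurka (1.27). The largest falls were of Map2k6 (-1.26, a kinase of the p38 pathway), Cib3 (-1.02), Ppp1r3c (-0.99, a glycogen-targeting subunit of protein phosphatase), Hal (-0.97), AW495222 (-0.82), Agxt (-0.78, a peroxisomal aminotransferase), Nr1i3 (-0.76, the xenobiotic receptor CAR) and Plk2 (-0.73). Gpt, alanine aminotransferase, fell by 0.62 and Ftcd, of histidine breakdown, by 0.46.

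Pericentral markers fell, with 3 of 16 lower and 0 higher (10 lower adjusted over the list alone), a median of -0.30 and camera adjusted p = 1.86e-10 (adjusted p = 0.0246 with an estimated correlation). Gulo fell by 0.60, Tbx3 by 0.59 and Lect2 by 0.47. Of 19 cholesterol synthesis genes 0 passed limma's threshold, though 6 fell adjusted over the list alone (median -0.23, camera adjusted p = 1.48e-07, and adjusted p = 0.137 with an estimated correlation). Of 19 bile acid genes 0 passed limma's threshold and 7 fell adjusted over the list alone (median -0.20, camera adjusted p = 1.53e-07, and adjusted p = 0.0947 with an estimated correlation). In the lipogenesis list, Srebf1, the transcription factor of fatty acid synthesis, fell by 0.53 and Pgd, of the pentose phosphate pathway, rose by 0.62 (1 of 29 in each direction, 1 higher and 5 lower adjusted over the list alone; median -0.12, camera adjusted p = 0.000284, and adjusted p = 0.259 with an estimated correlation). Markers of liver endothelial cells had a median of -0.30 with 0 of 18 past limma's threshold (6 fell adjusted over the list alone; camera adjusted p = 1.99e-07, and adjusted p = 0.259 with an estimated correlation). Stellate markers had a median of -0.20 with 0 of 20 past it (1 fell adjusted over the list alone; camera adjusted p = 2.12e-05, and adjusted p = 0.171 with an estimated correlation). Kupffer markers had a median of 0.04 (camera adjusted p = 0.486). Gluconeogenesis genes had a median of -0.15, with 1 of 18 lower and 0 higher (1 lower adjusted over the list alone; camera adjusted p = 0.0418, and adjusted p = 0.362 with an estimated correlation). The gene that fell was Slc37a4 (-0.47). This list call ended without Adeno-Cre fasted replicate 3 (adjusted p = 0.0551), Adeno-Cre fed replicate 3 (adjusted p = 0.528) or Adeno-GFP fed replicate 3 (adjusted p = 0.12) and with dim probe sets left out, and Slc37a4 lost its call without Adeno-Cre fasted replicate 2, Adeno-Cre fed replicates 1 or 3 or any of the Adeno-GFP fed arrays. Pck1 changed by -0.27 (adjusted p = 0.565), G6pc by -0.40 (adjusted p = 0.658), Ppargc1a by -0.21 (adjusted p = 0.693), Tat by -0.50 (adjusted p = 0.409) and Cps1 by -0.06 (adjusted p = 0.813).

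In fed mice 331 of 22180 genes passed limma's threshold, 239 higher and 92 lower. The count was 31 without Adeno-GFP fed replicate 3, 42 without Adeno-GFP fed replicate 1, and 114, 151 and 83 without Adeno-Cre fed replicates 1, 2 and 3. Of the 37 named genes that passed, 8 did so without each array in turn: BC023105, Bub1b, Dcxr, Gbp10, Igtp, Irgm2, Map2k6 and Rtp4.
The list members past the threshold moved with the same arrays. Without Adeno-GFP fed replicate 3, Adeno-GFP fed replicate 1, Adeno-Cre fed replicate 1 and Adeno-Cre fed replicate 3, in that order, the interferon genes numbered 3, 4, 14 and 14 and the cell cycle genes 1, 3, 6 and 5. In the same order the amino acid genes numbered 0, 0, 2 and 0 and the pericentral genes 0, 0, 1 and 0. Without Adeno-Cre fed replicate 2, the cell cycle genes numbered 7 and the amino acid genes 4, and without Adeno-GFP fasted replicate 2 the cell cycle genes numbered 23. The endothelial median was -0.17 without Adeno-Cre fed replicate 2, the lipogenesis median -0.19 without Adeno-Cre fed replicate 1 or Adeno-GFP fed replicate 1 and -0.18 without Adeno-Cre fed replicate 2, and the gluconeogenesis median -0.05 without Adeno-Cre fed replicate 3.

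The Adeno-Cre changes of the 2 diets were set against each other over all genes. Of the 502 genes that rose in fasted mice, 153 also rose in fed mice, where 5.41 would be shared by independent lists, and 479 (95.4%) had a positive change there. Of the 107 that fell, 18 also fell in fed mice (0.44 for independent lists) and 89 (83.2%) had a negative change. No gene passed in opposite directions. Across 22180 genes, which are not independent replicates, the changes had a Pearson correlation of 0.508 and a Spearman correlation of 0.281. For comparison, 100 random pairs of orthogonal contrasts of the within-group residuals, which hold no group effect, gave -0.215 to 0.203 and -0.224 to 0.205. The same 100 residual pairs served all 3 such relations computed.

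**Figure D2:**
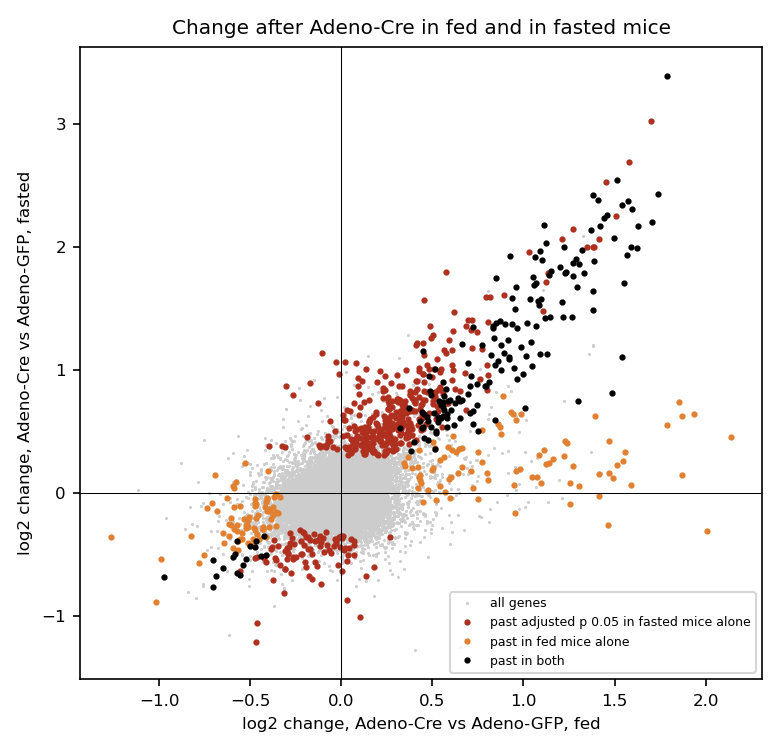
Log2 change after Adeno-Cre of each of the 22180 genes, in fed mice on the horizontal axis and in fasted mice on the vertical axis. Each point is a gene, coloured by the comparisons in which it passed limma's adjusted p of 0.05; the Pearson correlation across genes was 0.508.

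Averaged over both diets, 1239 genes passed, 788 higher and 451 lower, and 119 rose and 0 fell by at least 2-fold. Here 34 of 37 cell cycle genes rose and 0 fell (median 1.29, camera adjusted p = 5.73e-48, and adjusted p = 0.088 with an estimated correlation). Of the interferon genes 20 of 38 rose and 0 fell (median 0.65, camera adjusted p = 1.13e-27, and adjusted p = 0.105 with an estimated correlation), and 24 of 46 amino acid genes fell and 0 rose (median -0.24, camera adjusted p = 1.75e-17, and adjusted p = 0.105 with an estimated correlation). Adjusted over the list alone, 35 cell cycle genes rose and 2 fell, 29 interferon genes rose, and 33 amino acid genes fell. Pericentral markers fell, 11 of 16 with 0 higher (12 lower adjusted over the list alone; median -0.27, camera adjusted p = 3.43e-09, and adjusted p = 0.0378 with an estimated correlation). Of the 32 p53 targets 7 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.14, camera adjusted p = 1.98e-05, and adjusted p = 0.088 with an estimated correlation). Of 20 stellate markers 3 fell and 0 rose (15 fell adjusted over the list alone; median -0.20, camera adjusted p = 5.14e-07, and adjusted p = 0.113 with an estimated correlation). Endothelial markers had a median of -0.16 with 0 of 18 past limma's threshold (0 adjusted over the list alone; camera adjusted p = 0.000424, and adjusted p = 0.433 with an estimated correlation), and -0.11 without Adeno-Cre fed replicate 2. The stellate members numbered 5 without Adeno-Cre fasted replicate 3 and 1 without Adeno-Cre fasted replicates 1 or 2, Adeno-Cre fed replicate 2, Adeno-GFP fasted replicate 1 or Adeno-GFP fed replicate 3. The count of genes was 824 without Adeno-GFP fed replicate 3. The amino acid members numbered 13 without Adeno-GFP fed replicate 3 and 14 without Adeno-Cre fed replicate 3. The pericentral members numbered 6 without Adeno-GFP fed replicate 1 and 7 without Adeno-GFP fed replicate 3, Adeno-GFP fasted replicate 1 or Adeno-Cre fed replicates 1 or 3. The p53 targets that fell numbered 4 without Adeno-Cre fasted replicate 2 or Adeno-GFP fed replicate 1, and 3 without Adeno-Cre fed replicates 2 or 3, Adeno-GFP fasted replicate 1 or Adeno-GFP fed replicate 2. Over all fits without 1 array these targets numbered 3 to 5, the pericentral members 6 to 9 and the amino acid members 13 to 23. The full counts of 7, 11 and 24 were thus not reached without any 1 array.

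The fourth question was what fasting did in livers that received Adeno-GFP. Genes of lipid and sterol synthesis fell and genes of fatty acid oxidation rose. Hsd3b5, a male-biased steroid dehydrogenase of mouse liver (probe set 17408315), averaged 6.38 ± 0.42 (SD, n = 3) in fasted and 10.97 ± 0.18 in fed livers, a difference of -4.59 (SE 0.34, limma adjusted p = 3.31e-05) whose size is uncertain because the fasted level is close to the array medians. Of 19 cholesterol synthesis genes 13 fell and 0 rose (median -0.66, camera adjusted p = 4.26e-23, and adjusted p = 0.051 with an estimated correlation), led by Fdps (-1.82), Nsdhl (-1.54) and Cyp51 (-1.42, lanosterol demethylase). Of 29 lipogenesis genes 18 fell and 1 rose (median -0.57, camera adjusted p = 7.98e-20, and adjusted p = 0.0646 with an estimated correlation), among them Fasn (-1.65, fatty acid synthase), Pklr (-1.19, liver pyruvate kinase) and Me1 (-1.12, malic enzyme). Of 38 genes of fatty acid oxidation and ketogenesis 18 rose and 0 fell (median 0.38, camera adjusted p = 2.16e-19, and adjusted p = 0.172 with an estimated correlation), among them Cyp4a31 (2.15), Cyp4a14 (1.77), Acot1 (1.13, an acyl-CoA thioesterase) and Acadm (0.53, medium-chain acyl-CoA dehydrogenase). Adjusted over the list alone, 16 cholesterol genes fell, 20 lipogenesis genes fell and 1 rose, and 26 oxidation genes rose.

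Other large rises in fasted Adeno-GFP livers were of Trim43c (2.66), Fam107a (1.93, and 0.64 in its other probe set), Cyp17a1 (1.89, steroid 17-hydroxylase), Mt2 (1.70, a metallothionein), Gadd45g (1.53) and Insig2 (1.45, which retains the sterol sensor in the endoplasmic reticulum). Other large falls were of Fabp5 (-3.37, a fatty acid binding protein), Ugt2b38 (-3.16), Serpina4-ps1 (-3.11), Cyp2c55 (-2.49, and -0.385 in its other probe set), Gstm3 (-2.24), Shcbp1 (-2.19) and Serpina7 (-2.06, thyroxine-binding globulin). The lower group mean of Shcbp1, Ugt2b38, Fam107a, Gadd45g, Bub1 and Serpina12 lay under 6.26, the lowest array median, so the sizes and ranks of these changes are uncertain. Of 22 growth hormone and STAT5 targets 9 fell and 0 rose (10 fell adjusted over the list alone; median -0.43, camera adjusted p = 3.28e-09, and adjusted p = 0.125 with an estimated correlation), including Keg1 (-1.58) and Serpina12 (-1.27). Of 37 cell cycle genes 9 fell and 0 rose (26 fell adjusted over the list alone; median -0.55, camera adjusted p = 1.47e-19, and adjusted p = 0.295 with an estimated correlation), including Kif11 (-1.41), Nusap1 (-1.26), Bub1 (-1.23) and Ccnd1 (-0.75, cyclin D1). The cell cycle fall and the cell cycle rise after Adeno-Cre in fasted mice share the Adeno-GFP fasted arrays, with opposite sign. Of 46 amino acid genes 7 rose and 0 fell (15 rose adjusted over the list alone; median 0.17, camera adjusted p = 5.61e-10, and adjusted p = 0.324 with an estimated correlation), including Gldc (0.84, glycine decarboxylase), Oat (0.76) and Aass (0.72). Endothelial markers had a median of -0.27 with 0 of 18 past limma's threshold (0 adjusted over the list alone; camera adjusted p = 0.000225, and adjusted p = 0.522 with an estimated correlation). The 20 genes expressed by all leukocytes had a median of -0.15 (bootstrap interval -0.20 to -0.002), with 1 lower and 0 higher. Of 18 gluconeogenesis genes 2 rose and 0 fell (5 rose adjusted over the list alone; median 0.10, camera adjusted p = 0.00773, and adjusted p = 0.333 with an estimated correlation), Creb3l3 (0.345, a liver transcription factor) and Ppargc1a. Ppargc1a, a coactivator of the fasting response, rose by 0.80 (adjusted p = 0.0272), while Pck1 changed by 0.39 (adjusted p = 0.262), G6pc by -0.24 (adjusted p = 0.751) and Tat by 0.29 (adjusted p = 0.598).

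Fasting moved 682 genes past limma's threshold in Adeno-GFP livers, 267 higher and 415 lower, with 29 rising and 68 falling by at least 2-fold. Of the 71 named genes that passed, 48 did so without each array in turn, and Ppargc1a and Creb3l3 lost their calls without any 1 of the 6 arrays compared. The count was 412, 441 and 379 without Adeno-GFP fasted replicates 1, 2 and 3, and 308 and 275 without Adeno-GFP fed replicates 1 and 2. Without those 5 arrays in the same order, the cell cycle genes that fell numbered 15, 4, 3, 4 and 2. The oxidation genes that rose numbered 9 without Adeno-GFP fasted replicate 2, 11 without Adeno-GFP fed replicate 1 and 9 without Adeno-GFP fed replicate 2. The growth hormone targets that fell numbered 4 without Adeno-GFP fed replicate 1. The amino acid genes that rose numbered 3 without Adeno-GFP fasted replicate 1, 4 without Adeno-GFP fed replicate 1 and 3 without Adeno-GFP fed replicate 2.

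The fifth question was what fasting did in livers that received Adeno-Cre. Hsd3b5 fell here too (log2 change -5.14 in the deposited values, SE 0.34, limma adjusted p = 3.17e-05), from 10.36 ± 0.27 to 5.22 ± 0.86 (SD, n = 3). Of 38 oxidation and ketogenesis genes 19 rose and 0 fell (median 0.40, camera adjusted p = 7.28e-22, and adjusted p = 0.119 with an estimated correlation), including Cyp4a14 (2.07), Cyp4a31 (1.40), Ehhadh (1.19, a peroxisomal oxidation enzyme) and Acot2 (0.72). Of 19 cholesterol genes 9 fell and 0 rose (median -0.45, camera adjusted p = 1.32e-21, and adjusted p = 0.0667 with an estimated correlation), including Fdps (-1.87), Nsdhl (-1.42) and Cyp51 (-1.29). Of 38 interferon genes 21 fell and 0 rose from fed to fasted Adeno-Cre livers (median -0.92, camera adjusted p = 4.78e-28, and adjusted p = 0.119 with an estimated correlation), including Rtp4 (-1.38), Parp14 (-1.29) and Igtp (-1.03). Adjusted over the list alone, 27 oxidation genes rose, 16 cholesterol genes fell and 32 interferon genes fell. The interferon fall and the interferon rise after Adeno-Cre in fed mice share the Adeno-Cre fed arrays, with opposite sign, so they are not separate findings.

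Of 46 amino acid genes 14 rose and 0 fell (23 rose adjusted over the list alone; median 0.25, camera adjusted p = 3.22e-18, and adjusted p = 0.119 with an estimated correlation), including Gldc (0.86), Oat (0.81), Gpt (0.72) and Ftcd (0.54). Of 29 lipogenesis genes 9 fell and 1 rose (16 and 2 adjusted over the list alone; median -0.35, camera adjusted p = 1.65e-10, and adjusted p = 0.119 with an estimated correlation), including Scd1 (-0.80, stearoyl-CoA desaturase), Pklr (-0.78) and Me1 (-0.75). Growth hormone and STAT5 targets fell, 6 of 22 with 0 higher (8 fell adjusted over the list alone; median -0.34, camera adjusted p = 4.78e-07, and adjusted p = 0.119 with an estimated correlation), including Keg1 (-1.75) and Selenbp2 (-1.65). Kupffer cell markers had a median of -0.26 with 1 of 19 lower and 0 higher (7 lower adjusted over the list alone, camera adjusted p = 1.91e-05, and adjusted p = 0.286 with an estimated correlation). The gene past the threshold was Mpeg1 (-0.81, perforin-2). The 20 genes expressed by all leukocytes also lay lower, with a median of -0.31 (bootstrap interval -0.39 to -0.17) and 2 past the threshold. The cell cycle list gave no call (median -0.19, camera adjusted p = 0.289). Other large rises were of Cyp2b10 (1.55), Hnf4aos (1.54), Slc16a5 (1.48), Slco1a4 (1.41, an organic anion transporter), Nipal1 (1.41) and Defb1 (1.39, a defensin). Other large falls were of Serpina4-ps1 (-3.58), Ugt2b38 (-3.57), Fabp5 (-2.69), Gbp10 (-2.17), Ifit1 (-1.91) and BC023105 (-1.87). The lower group mean of Hsd3b5, Ugt2b38 and Cyp2b10 lay under 6.26, the lowest array median, so the sizes and ranks of these changes are uncertain. Of 18 gluconeogenesis genes 2 rose and 0 fell (4 rose adjusted over the list alone; median 0.11, camera adjusted p = 0.00127, and adjusted p = 0.286 with an estimated correlation). These were Ppargc1a (0.78, adjusted p = 0.0329) and Tpi1 (0.41, triose phosphate isomerase), while Pck1 changed by 0.35 (adjusted p = 0.328).

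In Adeno-Cre livers 592 genes passed between fasted and fed, 333 higher and 259 lower, and 43 of the 70 named genes that passed did so without each array in turn. Ppargc1a missed the threshold without Adeno-Cre fasted replicates 1 or 3 or Adeno-Cre fed replicates 1 or 3. The gluconeogenesis members that rose numbered 0 without Adeno-Cre fasted replicate 1 or Adeno-Cre fed replicates 1 or 3 and 1 without Adeno-Cre fasted replicate 2, and the list call ended without Adeno-Cre fed replicate 3 (adjusted p = 0.0906). Without Adeno-Cre fasted replicate 3 the gluconeogenesis median was 0.19 and the Kupffer median -0.43. The count was 207 and 246 without Adeno-Cre fasted replicates 1 and 2, and 243, 330 and 283 without Adeno-Cre fed replicates 1, 2 and 3. Without those 5 arrays in the same order, the oxidation genes that rose numbered 6, 5, 6, 5 and 7. The interferon genes that fell numbered 8 without Adeno-Cre fasted replicate 2, 13 without Adeno-Cre fasted replicate 3 and 8 without Adeno-Cre fed replicate 1. The lipogenesis genes that fell numbered 4 without Adeno-Cre fasted replicate 1, Adeno-Cre fasted replicate 2 or Adeno-Cre fed replicate 1. The amino acid genes that rose numbered 5 without Adeno-Cre fasted replicate 1, 9 without Adeno-Cre fed replicate 1 and 7 without Adeno-Cre fed replicate 3. Of the 267 genes that rose with fasting after Adeno-GFP, 144 also rose after Adeno-Cre (4.01 for independent lists), and of the 415 that fell, 112 also fell (4.85 for independent lists), with 1 gene past the threshold in opposite directions. The 2 fasting effects correlated at 0.512 (Pearson) and 0.345 (Spearman) across genes, above the -0.215 to 0.203 and -0.224 to 0.205 of the 100 residual pairs.

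**Figure D3:**
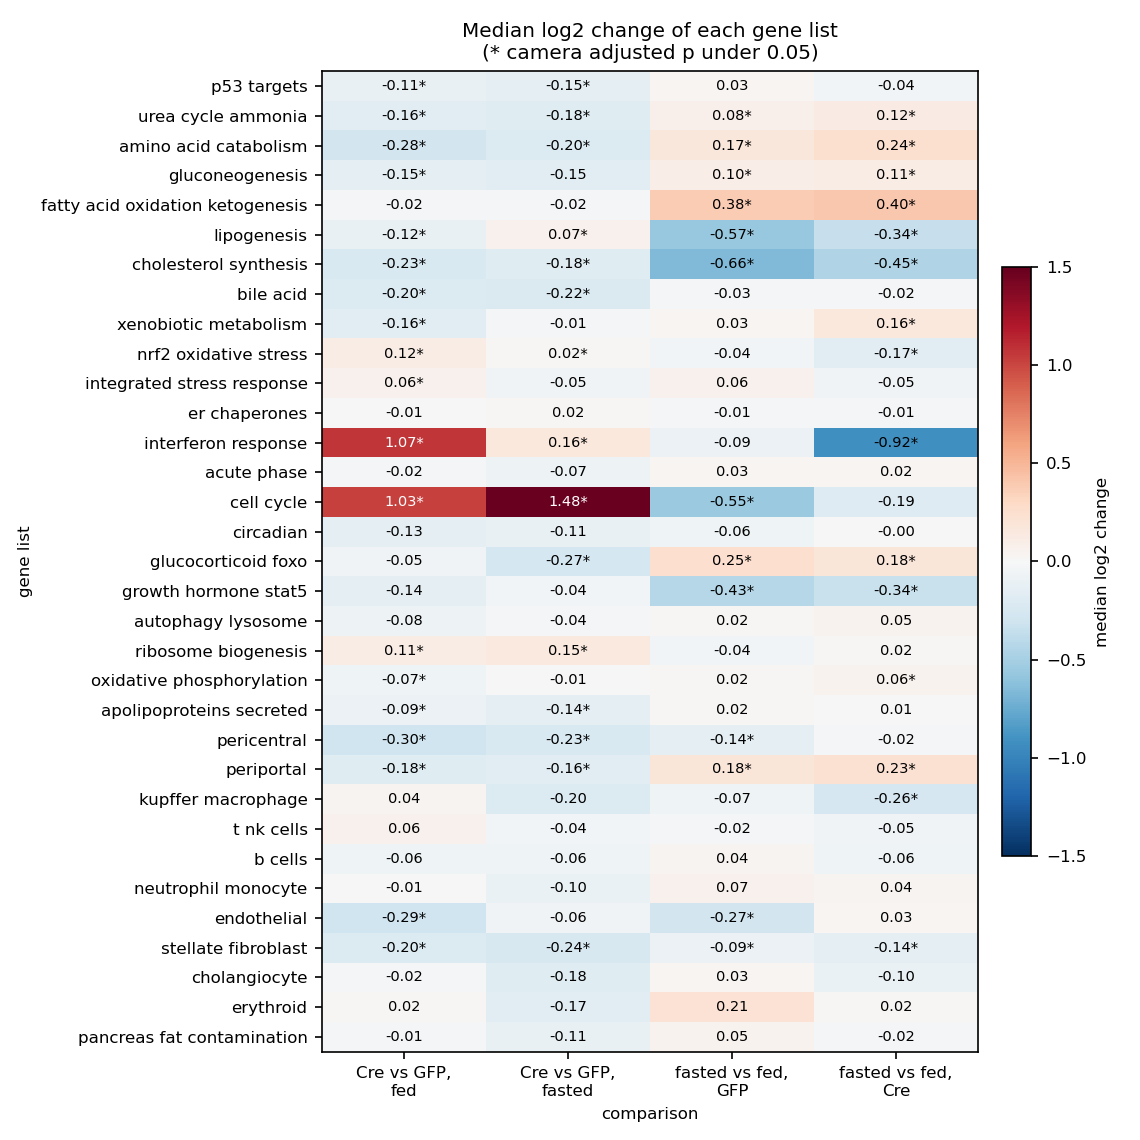
Median log2 change of the measured members of each of 33 gene lists (vertical axis) in 4 comparisons (horizontal axis), with red for higher and blue for lower. Each cell prints its median, and a star marks a camera adjusted p under 0.05; the cell cycle list had medians of 1.03 and 1.48 after Adeno-Cre, and the cholesterol synthesis list -0.66 and -0.45 with fasting.

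The sixth question was whether the effect of Adeno-Cre differed between diets, tested as an interaction. By limma, 1 of 22180 genes passed and 1676 had an unadjusted p under 0.05. That gene was Slc44a3, a choline transporter-like protein (probe set 17409893), with levels of 8.39 ± 0.11 (SD, n = 3) after Adeno-Cre and 7.50 ± 0.08 after Adeno-GFP in fasted mice, and 7.92 ± 0.07 and 8.10 ± 0.13 in fed mice. Its interaction was 1.07 (SE 0.13, adjusted p = 0.0481). Among genes that did not pass, Ccl12 had an interaction of -1.29, Gadd45g of -1.11, Gstm3 of 1.22, Serpina3i of 0.78 and Catsperb of 0.71, each at adjusted p = 0.238, and Ifit1 one of -2.32 (adjusted p = 0.404). Of the interferon list 0 of 38 members passed limma's threshold (0 higher and 23 lower adjusted over the list alone), and its median was -0.81 (camera adjusted p = 2.59e-22, and adjusted p = 0.732 with an estimated correlation). The cell cycle list had 0 of 37 past it (5 higher adjusted over the list alone) and a median of 0.59 (camera adjusted p = 1.76e-15, and adjusted p = 0.732 with an estimated correlation). The lipogenesis list had 0 of 29 (4 higher adjusted over the list alone) and a median of 0.23 (camera adjusted p = 7.03e-07, and adjusted p = 0.732 with an estimated correlation). The p53 targets had a median of 0.00 (camera adjusted p = 0.904).

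Slc44a3 passed without Adeno-GFP fed replicate 3 and lost its call without each of the other 11 arrays. The count of genes was then 0 by limma, except that 1 other gene passed without Adeno-GFP fasted replicate 3. Simulated interactions of 0.5, 1, 2 and 3 on the log2 scale were recovered at rates of 12%, 86%, 98% and 100%. That simulation changed 200 genes at once and gave 155 calls. The adjustment is stricter where few genes pass, as in the real interaction. The rates therefore do not show that real interactions of these sizes would have passed.

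The last relation set the Adeno-Cre effect averaged over diets against the fasting effect averaged over injections. Across the 22180 genes the Pearson correlation was -0.216 and the Spearman correlation -0.073, where the 100 residual pairs gave Pearson values of -0.215 to 0.203 and Spearman values of -0.224 to 0.205. Gadd45g rose by 1.53 with fasting after Adeno-GFP and fell by 1.01 after Adeno-Cre in fasted mice, but both values rest on the Adeno-GFP fasted arrays, with opposite sign. Its change after Adeno-Cre in fed mice was 0.10 (adjusted p = 0.81).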

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

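Of the tests here, the list test fry was chosen only after the results were seen, and the leukocyte genes were listed after the comparisons were seen. A test of the difference between diets itself gave a call for Slc44a3 and for 7 gene lists, none of which held in every alternative. For Slc44a3 the interaction was 1.07 (limma adjusted p = 0.0481); over its 17 alternatives that p ran from 0.00997 to 0.312. The list medians of the interaction were -0.81 for interferon response, 0.59 for cell cycle, 0.23 for lipogenesis, 0.26 for endothelial markers (camera adjusted p = 0.000538), -0.32 for Kupffer markers (0.0187), 0.081 for amino acid breakdown (0.0256) and 0.12 for xenobiotic metabolism (0.0425). None of the 7 lists held with an estimated correlation (adjusted p = 0.732 to 0.819) or with fry (0.409 to 0.73). Without Adeno-GFP fasted replicate 2 the cell cycle median was 0.37, the endothelial 0.17 and the xenobiotic 0.22, without Adeno-GFP fasted replicate 1 the amino acid median was 0.125, and without Adeno-Cre fed replicate 1 the endothelial median was 0.40. Leaving out 1 array ended the endothelial call without Adeno-Cre fed replicate 2 (median 0.13) and the Kupffer call without Adeno-Cre fasted replicate 2 (-0.17), Adeno-Cre fed replicates 1 (-0.24) or 3 (-0.22) or Adeno-GFP fasted replicate 1 (-0.16). Slc44a3 lost its call without each array but Adeno-GFP fed replicate 3. The amino acid call ended without Adeno-Cre fasted replicate 1, Adeno-Cre fed replicate 3, Adeno-GFP fasted replicates 2 or 3 or Adeno-GFP fed replicate 3 (adjusted p = 0.0743 to 0.369), with medians of 0.046 without Adeno-Cre fed replicate 3 and 0.048 without Adeno-GFP fed replicate 3. The xenobiotic call ended without Adeno-Cre fasted replicate 2, Adeno-Cre fed replicate 3, Adeno-GFP fasted replicates 1 or 3 or any of the Adeno-GFP fed arrays (adjusted p = 0.0512 to 0.461), with medians of 0.048 without Adeno-Cre fed replicate 3 and 0.078 without Adeno-GFP fasted replicate 1.

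The score of the interferon list averaged 0.75 ± 0.36 (SD, n = 3) in Adeno-Cre fed livers, -0.12 ± 0.14 in Adeno-Cre fasted livers, -0.28 ± 0.15 in Adeno-GFP fed livers and -0.34 ± 0.24 in Adeno-GFP fasted livers. A single array was argued against: over 12 fits without 1 array, the median of the interaction closest to 0 was -0.60, against -0.81 with all. More leukocytes in the fed livers stay open. The 20 genes expressed by all leukocytes had an interaction median of -0.16, with an interval of -0.23 to -0.10. Its lower end of -0.234 stayed above the bound of -0.25 set beforehand. The whole interval nevertheless lay on the negative side, the direction that more leukocytes in fed Adeno-Cre livers would give. It draws genes, taken as independent, and does not measure the spread between mice, so this test cannot decide. The same genes were lower with fasting, by a median of -0.31 after Adeno-Cre (interval -0.39 to -0.17) and -0.15 after Adeno-GFP (-0.20 to -0.002). A change in Kupffer cells (-0.32), a difference in the reaction to the adenovirus between injections and a diet-dependent effect of p53 loss stay open and may act together, and the last is a hypothesis only.

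For the interaction as a whole, the real split gave 1 gene by limma (1676 at an unadjusted p under 0.05), and 4 of 100 splits of the 12 arrays, the real one included, gave at least 1. Chance is not taken as excluded by a count of 1, which other splits reached and which rests on Slc44a3. The highest other split gave 1239 genes: it exchanged the injections in 1 diet, so that it measured the average Adeno-Cre effect, a structure of the samples.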

How the results depend on the processing

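Fry was added after seeing the data, as were the test of hepatocyte share and its fits without 1 array described below. Leaving out dim probe sets (12401 genes tested) gave 919 genes for Adeno-Cre in fasted and 554 in fed mice, and 1094 and 984 for fasting after Adeno-GFP and Adeno-Cre; a trended and robust prior gave 939, 539, 1038 and 935. Fitting only the groups compared, with fewer arrays behind the spread, gave 320, 145, 394 and 212. All 41345 probe sets as features gave 91 for Adeno-Cre in fed mice and 388 and 332 for fasting, and 0 for the interaction by limma (1676 genes at an unadjusted p under 0.05 with named genes), as did quantile normalisation again (0). Beyond fewer arrays and other numbers of features, the cause was not tested. Averaging probe sets kept each count within 1.5 times.

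With the replicate number as a block the counts were 531, 234, 1110, 587 and 552 for Adeno-Cre in fasted mice, in fed mice and averaged, and for fasting after Adeno-GFP and Adeno-Cre, and 0 for the interaction, and all 84 list calls kept their side. The numbers do not pair the mice: 2 of 18 same-number pairs correlated above 0.1 (range -0.09 to 0.15), and 5 of 12 arrays correlated best with their own number.

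Without each array in turn the counts ran from 355 to 800 (Adeno-Cre, fasted), 31 to 362 (fed), 824 to 1353 (averaged), 275 to 720 (fasting, Adeno-GFP), 207 to 713 (fasting, Adeno-Cre) and 0 to 1 (interaction). A few changes that had not passed changed sign: in the interaction Cps1 (-0.052 to 0.02), Ppargc1a (-0.25 to 0.12), Pck1 (-0.27 to 0.12), G6pc (-0.32 to 0.41), Tat (-0.18 to 0.42) and Cdkn1a (-0.19 to 0.69); with fasting after Adeno-Cre G6pc (-0.56 to 0.17) and Mdm2 (-0.068 to 0.037); after Adeno-Cre in fed mice G6pc (-0.667 to 0.061) and Ppargc1a (-0.348 to 0.017), and in fasted mice Cdkn1a (-0.862 to 0.012). Of the 404 gene values in 12 such fits, 4317 kept their side, 461 lost the threshold and 46 gained it. Among list calls, 958 kept their side and 50 did not; with dim probe sets left out 74 of 84 held, with quantile normalisation 80, with averaged probe sets 83, with a trended prior 84, with an estimated correlation 2 and with fry 57. The alternative for Trp53 was not run, since no probe set names it alone.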

Other observations

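The test of hepatocyte share here, its fits without 1 array and the list test fry were chosen after the results were seen, and the leukocyte genes were listed after the comparisons were seen. Several gene groups changed in part with fasting after Adeno-GFP without a list call. Of 19 clock genes 2 rose and 2 fell (3 and 4 adjusted over the list alone; median -0.06, camera adjusted p = 0.423): Clock (0.55) and Ciart (0.73) rose, and Bhlhe40 (-0.83) and Wee1 (-0.70), a kinase that delays mitosis, fell. Of 27 acute phase genes 5 rose and 1 fell (9 and 3 adjusted over the list alone; median 0.03, camera adjusted p = 0.102), with Mt2, Mt1 (1.22) and Lbp (0.90, lipopolysaccharide binding protein) higher and Lifr (-0.57) lower. Of 28 autophagy and lysosome genes the protease gene Ctsl rose (0.30) and the kinase gene Ulk2 fell (-0.58), with a median of 0.02 (camera adjusted p = 0.928). Of 22 chaperone genes of the endoplasmic reticulum, Sec61b (-0.71) and Ero1b (-0.46) fell (median -0.01, camera adjusted p = 0.224). The oxidative phosphorylation list had a median of 0.06 with fasting after Adeno-Cre (2 of 39 higher, 0 lower, camera adjusted p = 0.000783, and adjusted p = 0.298 with an estimated correlation), and Ndufv1 (0.37) and Sdhd (0.36) were the 2 that rose. The median was 0.09 without Adeno-Cre fasted replicate 3. The number that rose was 0 without Adeno-Cre fasted replicates 1 or 2 or any of the Adeno-Cre fed arrays, and 1 without any of the Adeno-GFP fasted arrays or Adeno-GFP fed replicate 2. With fasting after Adeno-GFP, Ciart lost its call without Adeno-GFP fasted replicate 3 or Adeno-GFP fed replicates 1 or 2, Wee1 without Adeno-GFP fasted replicates 1 or 2 or Adeno-GFP fed replicates 1 or 2, and Ctsl without any 1 of the 6 Adeno-GFP arrays. Ero1b lost its call without any 1 of those 6, Adeno-Cre fasted replicate 1 or Adeno-Cre fed replicate 3. The acute phase genes that rose numbered 3 without Adeno-GFP fasted replicate 1 or Adeno-GFP fed replicates 1 or 2.

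Of 20 stellate markers 3 fell and 1 rose with fasting after Adeno-GFP (5 and 1 adjusted over the list alone), and 4 fell and 1 rose after Adeno-Cre (4 and 1 adjusted over the list alone). Lrat, which esterifies retinol, fell by 0.76 after Adeno-GFP, Col1a2 by 0.55 (-0.03 in its other probe set) and Col14a1 by 0.60. After Adeno-Cre Col3a1 fell by 0.76, Col1a2 by 0.62 (-0.27 in its other probe set), Col14a1 by 0.62 and Lrat by 0.516, the last named here after its values were seen. Pdgfra rose by 0.42 and 0.45. The list medians were -0.09 (camera adjusted p = 0.0251, and adjusted p = 0.522 with an estimated correlation) and -0.14 (0.00574, and adjusted p = 0.367 with an estimated correlation), and the calls ended without Adeno-GFP fasted replicates 2 (median -0.07) or 3 (-0.06) and without Adeno-Cre fasted replicate 2 (-0.08). Without Adeno-GFP fasted replicate 1 the median after Adeno-GFP was -0.14, and without Adeno-Cre fasted replicate 3 that after Adeno-Cre was -0.21. After Adeno-GFP, 1 marker fell without Adeno-GFP fasted replicates 2 or 3 or any of the Adeno-GFP fed arrays, Pdgfra lost its call without any of the Adeno-GFP fasted arrays or Adeno-GFP fed replicates 2 or 3, and Col1a2 lost its call with averaged probe sets. After Adeno-Cre, 1 marker fell without Adeno-Cre fasted replicates 1 or 2 or Adeno-Cre fed replicates 2 or 3 and 2 without Adeno-Cre fed replicate 1, and Pdgfra lost its call without any of the Adeno-Cre fasted arrays or Adeno-Cre fed replicates 1 or 3. Averaged over diets after Adeno-Cre, 4 of 16 periportal genes fell and 1 rose (8 and 2 adjusted over the list alone; median -0.19, camera adjusted p = 0.00337, and adjusted p = 0.301 with an estimated correlation), and 0 rose without any 1 of 11 arrays, all but Adeno-Cre fasted replicate 3. Of 22 oxidative stress genes 4 rose and 0 fell (5 rose adjusted over the list alone; median 0.11, camera adjusted p = 0.000345, and adjusted p = 0.088 with an estimated correlation). Markers of T and NK cells, B cells, neutrophils and monocytes, bile duct cells, and pancreas or fat gave no camera call in any comparison, with at most 1 member past limma's threshold in each direction. By fry the B cell list was lower after Adeno-Cre in fasted mice (adjusted p = 0.0422) and averaged (adjusted p = 0.0106), and the pancreas or fat list averaged (adjusted p = 0.0487). The medians of these lists, from T and NK cells to pancreas or fat, after Adeno-Cre in fed mice were 0.06, -0.06, -0.01, -0.02 and -0.01. In the same order, 9 of 25, 2 of 13, 6 of 18, 5 of 12 and 5 of 15 genes lay above the median probe set level. Most of these genes were thus not shown to be above background. The lack of camera calls does not show that these cells were unchanged, and the fry calls carry the same limit. Only 4 genes of the erythroid list were measured, and it was not tested.

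For the rise of cell cycle genes after Adeno-Cre in fasted mice, more leukocytes would raise the 20 genes expressed by all leukocytes. Their median was instead -0.09, with an interval of -0.148 to -0.058, which argues weakly against a larger share of leukocytes. The interval draws genes, taken as independent, and does not measure the spread between mice. It does not show which cells divided. A single array was argued against as well, since at least 30 of the 33 genes stayed past the threshold in each of the 6 fits without 1 of its arrays. A biological explanation, division of liver cells after loss of p53, may apply, as a hypothesis; a difference between the viruses stays open and was not tested.

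For the fall of amino acid genes after Adeno-Cre in fed mice, a lower share of hepatocytes would raise markers of other cells. Endothelial markers instead had a median of -0.30 with an upper end of -0.228, and stellate markers one of -0.20 (-0.27 to -0.11). These intervals draw genes and do not measure the spread between livers. Endothelial scores were -0.09 ± 0.24 (SD, n = 3) after Adeno-Cre against 0.20 ± 0.03 after Adeno-GFP. Stellate scores were -0.02 ± 0.05 against 0.17 ± 0.01. The test was chosen after these medians were seen, so its outcome was known and it cannot decide. A lower share of hepatocytes stays open. The values show only that endothelial and stellate markers did not rise, less clearly for the endothelial ones because their Adeno-Cre arrays spread widely. Without Adeno-Cre fed replicate 2 the endothelial median was -0.17 (upper end -0.09), and over the 6 fits without 1 array the upper ends of both lists stayed below 0, although neither list's call held with an estimated correlation (adjusted p = 0.259 and 0.171). Kupffer markers (0.04, interval -0.04 to 0.08) and genes expressed by all leukocytes (0.04, interval -0.005 to 0.08) lay near 0, but without Adeno-Cre fed replicate 2 the Kupffer median was 0.139 (interval 0.116 to 0.204), the direction a lower share of hepatocytes would give. The tables argue against a trend with probe set brightness as the cause of the amino acid fall. The list median of -0.28 lay below the 2.5th percentile (-0.07) of 10000 random lists matched on level, of which 0 were as low. Other hepatocyte lists were also called lower in fed mice, so the fall was not confined to amino acid genes. By camera these included pericentral markers (median -0.30, adjusted p = 1.86e-10), cholesterol synthesis (-0.23, 1.48e-07) and bile acid genes (-0.20, 1.53e-07). They also included secreted apolipoproteins (median -0.09, adjusted p = 7.93e-05), urea cycle (-0.16, 0.000766), periportal (-0.18, 0.00453) and xenobiotic genes (-0.16, 0.00363). The pericentral call held with an estimated correlation (camera adjusted p = 0.0246), and the others named here did not (0.0947 to 0.37). The periportal and xenobiotic calls ended without Adeno-Cre fed replicate 3. Fatty acid oxidation gave no call (-0.02, 0.378). An effect of p53 loss on these genes may remain, as a hypothesis, beside the difference between the viruses, which was not tested.

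The counts of genes were set against other splits of the same arrays. For Adeno-Cre averaged over diets, 1 of 100 splits gave as many genes, the real one, with 1239 against 2 in the highest other. This share under 0.05 argues against chance but does not exclude it. Most other splits mix the injections within a group, which adds any difference between them to the spread and lowers their counts. For the comparisons of 3 arrays against 3, 10 splits are too few for a share under 0.05: the real counts of 609, 331, 682 and 592 were reached by 1 split, and the highest other gave 0 by limma.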
